A study of Homo sapiens with 3 samples.

How the data were processed

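Total RNA of OECM1 cells stably carrying a scramble, Twist1 or Bmi1 hairpin vector was profiled on 1-colour Agilent human miRNA arrays (design 029297). Per the labels' protocols, 0.1 µg of RNA was dephosphorylated and labelled with Cy3, with spike-in RNAs added. Each group has 1 array, and each sample was placed in its group by the knockdown given in its labels.

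The spot files hold Cy3 intensities that the authors extracted with Agilent Feature Extraction 10.7.3.1, protocol miRNA_107_Sep09, per the file headers. The processed intensity of a spot is background-subtracted, is not scaled between arrays and can be negative. The deposited gene-level files give the total intensity of each miRNA. The deposited series value table holds intensities on a linear scale, uncentred and unscaled: all 908 of its values per array equal the gene-level totals. Differences are taken here as knockdown over control, or Bmi1 knockdown over Twist1 knockdown.

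From the 14907 spots of an array, of which 14192 are human (2446 probes, 4 to 16 spots each), those marked by the software as non-uniform or population outliers were left out: 7.27% on the control array, 7.36% on the Twist1 array and 8.05% on the Bmi1 array. No spot was saturated. Spots were averaged per probe and divided by the array's 75th percentile over the 356 human probes well above background on all 3 arrays, an intensity of 323, 401 and 315. A miRNA's level is the sum of its 1 to 4 probes, on the log2 scale. A probe was well above background when most of its kept spots were marked so, and a miRNA when any of its probes was. Negative control spots (182 per array) averaged 0.101, 0.885 and 1.34 intensity units, with SDs of 1.72, 2.59 and 2.40. The lowest intensity well above background was 7.93, 10.7 and 11.7. The number of arrays limits the precision: with 1 per group there is no estimate of variation between cultures or arrays. The median technical SE of a log2 difference was 0.034 for Twist1 and 0.038 for Bmi1.

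Differences were taken among miRNAs above background on both arrays and counted at 2-fold. A miRNA above background on 1 array of a comparison was given a bound, its brightest probe's level over the higher of the lowest level well above background and the dim probe's own level. Bounds were computed in the main setting alone. No test was run. Lists of 3 or more measured miRNAs were placed among 10000 random lists of the same size drawn from 5 bins of level, as a description of these arrays. The draws took single miRNAs, whereas members of a family or gene cluster can vary together. Such a list can therefore reach an extreme percentile more easily than the draws allow for. The 23 lists, the main setting and the rule for named miRNAs were fixed before the data were examined. The rule takes up to 10 miRNAs per direction (5 between the knockdowns) that are at least 2-fold different by more than 2 technical SE, with the brighter array at or above the median level and all measured probes agreeing in sign. It adds the 3 largest bounds per direction, let-7i, and up to 4 members per list with the highest mean level. It left other 2-fold miRNAs out, and those printed are stated to have been chosen after their values were seen.

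A choice about list names was also made after values were seen. The names miR-1974 and miR-1977 carry a version suffix on the array, so exact matching at first left them out of the list of sequences from other small RNAs. Matching the suffixed names changes where that list falls, and both versions are given below. miR-106a and miR-519a are not analysed here, and no viral probes were found on the array, so a planned list of them is empty and negative control probes served as the background check.

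The alternatives were normexp background correction with an offset of 50 (limma 3.58.1, R 4.3.3), 5 other scalings, 3 other ways to combine probes, the series value table, keeping outlier spots, 3 other filters and 2 other thresholds. On the control, Twist1 and Bmi1 arrays, 412, 415 and 370 of 2446 human probes were well above background. The 75th percentile of all human probes, 1 of the scalings, thus falls among probes not well above background. Signs stated to change with the scaling include this setting. The normexp alternative was planned on mean spot signals. The files have no such column, so median signals were used. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. On simulated arrays for the Twist1 comparison (267 miRNAs), 20 of 20 miRNAs changed 3-fold and 0 of 20 changed 1.5-fold passed the 2-fold threshold, as did 0 of 227 unchanged ones. The simulated spots came from the control array's probe means and spot spread, with 1 factor per array. They hold no other variation between arrays or cultures, so they do not give a rate of false calls between real arrays.

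The file headers name genome build hg19. The gene table used here is GRCh38.p14, so no coordinates are given and it served for names and for neighbouring or overlapping genes, without regard to strand. Of 228 miRNAs above background on any array, 177 matched 1 hairpin gene, 32 matched several and 19 none.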

Results

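MicroRNA (miRNA) levels were measured in OECM1 cells, an established human oral squamous carcinoma line, after stable transfection of pSUPER vectors that express a short hairpin RNA. The hairpin was directed against Twist1, a basic helix-loop-helix transcription factor that drives epithelial-mesenchymal transition, or against Bmi1, a component of Polycomb repressive complex 1. A vector with a scramble hairpin served as the control. Each of the 3 groups was measured on 1 array, so every difference below compares single arrays. No test was possible, no p-value is given, and errors (SE) come from the spread between spots of an array and are technical. The arrays carry no probes for the Twist1 and Bmi1 mRNAs, so the knockdowns could not be checked here.

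Of 887 human miRNAs on the array, 219 were well above background in the scramble control, 220 in the Twist1 knockdown and 198 in the Bmi1 knockdown, and 194 were on all 3 arrays. A few RNAs held much of the intensity. miR-21, an abundant miRNA of many carcinomas, made up 28.5% of the summed intensity in the control, 27.9% in the Twist1 knockdown and 26.8% in the Bmi1 knockdown. miR-1974, a sequence from a mitochondrial tRNA, made up 14.6%, 15.4% and 16.3% in the same order, and miR-720, a tRNA-derived sequence, 9.94%, 8.52% and 7.53%. Of the lists of miRNAs typical of other cell types, no member was above background on any array for the stromal (6 on the array), muscle (4), liver (1), pluripotent (8) and chromosome 19 placental-cluster (15) lists. Of 7 haematopoietic miRNAs, miR-223 was above background in the control alone. Of 7 neural miRNAs, 4 were above background on at least 1 array: miR-7, miR-9, miR-9* and miR-129-3p. Of 37 miRNAs of the imprinted 14q32 cluster, miR-494 was above background, with log2 differences from control of -0.07 (SE 0.08) in the Twist1 knockdown and 0.17 (SE 0.07) in the Bmi1 knockdown, both changing sign with the scaling.

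The first comparison asked which miRNAs differ when Twist1 is knocked down. let-7i, a member of the let-7 family of growth-restraining miRNAs, was 2.04-fold higher than in the control (log2 difference 1.03, SE 0.03). Higher levels were also seen for miR-762 (5.86-fold, log2 2.55, SE 0.05) and miR-1915 (4.38-fold, log2 2.13, SE 0.04), with log2 differences of 1.03 and 0.96 under normexp background correction. These 3 met the rule for named miRNAs. Of 211 miRNAs above background on both arrays, 8 were at least 2-fold higher and 1 was at least 2-fold lower. The other 5 higher miRNAs and the lower one fell outside that rule and were chosen after their values were seen. They were miR-874 (4.04-fold), miR-1225-5p (2.37-fold), miR-205 (2.28-fold), miR-1181 (2.22-fold) and miR-638 (2.21-fold), and miR-455-3p was 2.08-fold lower (log2 difference -1.06, SE 0.05). miR-205 represses the ZEB factors of epithelial-mesenchymal transition. Of the 2 probes each, 1 was above background on both arrays for miR-762, miR-874, miR-205, miR-1181 and miR-638, so their sums include a probe not above background on both. With the brightest probe alone the log2 differences of these 5 were 2.48, 1.79, 1.06, 1.21 and 1.01. With normexp correction the log2 differences were 0.27 for miR-874, 0.15 for miR-1225-5p, -0.02 for miR-205, 0.02 for miR-1181 and 0.09 for miR-638, and over 12 other settings the lowest were 1.25 for miR-874 and 0.90 for miR-205, both with log2 probe means, and at least 1.01 for the other 3. In the GRCh38.p14 annotation the hairpin genes of miR-762, miR-874, miR-1225-5p, miR-1181 and miR-638 overlap BCL7C, KLHL3, PKD1, CDC37 and DNM2. Most miRNAs differed little: the median log2 difference was -0.02 (quartiles -0.19 and 0.13), and 89.6% lay within 0.5 of 0.

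let-7i was read by 2 probes, with log2 differences of 1.08 and 0.97 in the Twist1 knockdown and of 1.11 and 1.07 in the Bmi1 knockdown. Its hairpin gene lies within MIRLET7IHG in the GRCh38.p14 annotation. let-7i exceeded the median of the other 8 let-7 members by 1.08 in the Twist1 knockdown and 1.03 in the Bmi1 knockdown. Of 6 scalings only quantile normalization, which is not a factor common to an array, could change this. With it the excess was at least 0.875. In the Twist1 knockdown let-7a had a log2 difference of -0.00 (SE 0.02), let-7d of 0.02 (SE 0.02) and let-7f of -0.02 (SE 0.02), and in the Bmi1 knockdown the values were 0.11 (SE 0.03), 0.12 (SE 0.02) and 0.00 (SE 0.03), all changing sign with the scaling. The median of the 8 members ran from -0.12 to 0.39 for Twist1 and from -0.33 to 0.12 for Bmi1 over the settings tried. For the whole list of 9 the Twist1 median was -0.04 (14.2nd percentile of random lists), also changing sign. let-7i itself stayed between 0.82 and 1.47 and between 0.70 and 1.15 over the settings tried. Published work on Twist1 and Bmi1 names let-7i, so its direction here is not independent evidence.

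**Figure D1:**
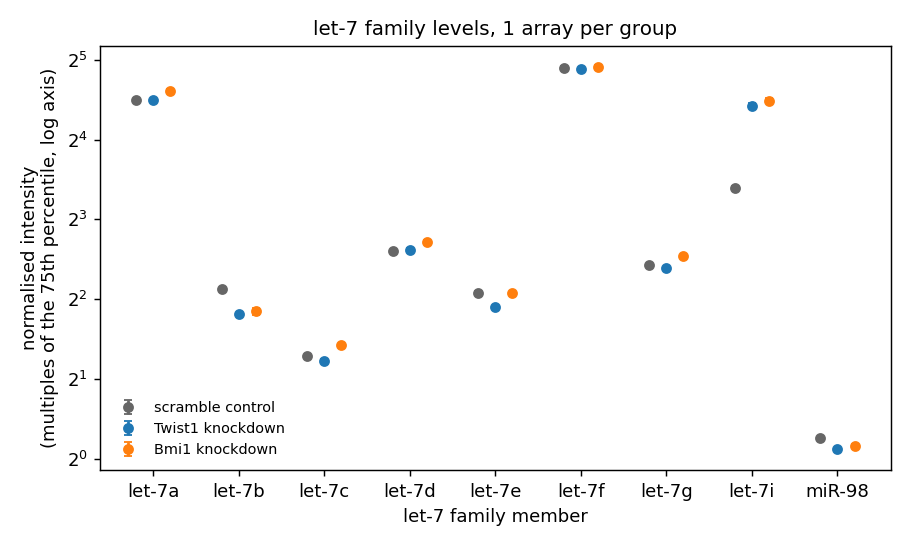
Normalised intensity of the 9 let-7 family members on the 3 arrays (y axis on a log scale, in multiples of each array's 75th percentile). Each point is 1 array, and technical SE bars are mostly smaller than the points. let-7i was 2.04-fold and 2.13-fold higher in the Twist1 and Bmi1 knockdowns, while the sign of the median of the other members depended on the scaling.

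Among the lists for Twist1, the miR-29 family, which targets collagen transcripts, stood highest. All 3 members were higher, miR-29a by 0.56 (log2, SE 0.02), miR-29c by 0.41 (SE 0.02) and miR-29b by 0.35 (SE 0.03). Their median of 0.41 lay at the 99.9th percentile of 10000 random lists matched on size and level, and exceeded the median of all miRNAs by 0.39 to 0.48 over 10 other settings. The random lists do not allow for family members that vary together, which limits this percentile and those of the other families. The cell-cycle-restraining miR-15/16 family had 4 of 5 measured members higher, with a median of 0.24 (99.5th percentile), which exceeded that of all miRNAs by 0.09 to 0.26 over the same settings. Its members differed in sign: miR-424 was at 0.56 (SE 0.01), miR-15b at 0.24 (SE 0.03) and miR-15a at -0.21 (SE 0.03), the last of which changed sign with the scaling. All 11 measured members of the cluster from miR-17 to miR-92a and its paralogs were above 0, from 0.04 to 0.18, with a median of 0.09 at the 96.6th percentile, but miR-19b and miR-20a changed sign under another scaling. The list median exceeded that of all miRNAs by 0.09 to 0.23 over 10 other settings. In the epithelial list of the miR-200 family, miR-205 and miR-203, the median of 6 measured members was 0.08 (86.7th percentile), turning to -0.03 with normexp correction. Relative to the median of all miRNAs the list lay at 0.07 to 0.14 over 10 other settings. Its member miR-200b was at 0.14 (SE 0.03), while miR-200c at 0.02 (SE 0.04) and miR-141 at -0.19 (SE 0.03) changed sign with the scaling. The medians were -0.03 for the miR-23/27/24 list, -0.15 for miR-30, -0.13 for the miR-183 cluster, 0.05 for miRNAs tied to epithelial-mesenchymal transition (miR-21 at -0.02, SE 0.02), 0.02 for miRNAs reported to target Bmi1, 0.05 for the p53-linked miR-34 list and 0.02 for neural miRNAs. Each lay within the central 95% of its random lists, and each of these 7 medians, and miR-21, changed sign under at least 1 other setting. miR-34a, within the p53-linked list, was at -0.72 (SE 0.08). miR-221 was at 0.13 (SE 0.02) and miR-222 at -0.12 (SE 0.03), and the hypoxia-induced miR-210 at -0.27 (SE 0.03), where miR-222 and miR-210 changed sign with the scaling.

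miRNAs above background on only 1 of the 2 arrays have a bound in place of a difference. In the Twist1 knockdown 9 such miRNAs were above background there alone and 8 in the control alone, of which 2 had a bound below 1, which shows no difference. miR-150* was at least 3.83-fold higher, miR-532-3p at least 1.51-fold and miR-502-3p at least 1.43-fold. miR-130a was at least 1.99-fold lower, miR-223 at least 1.31-fold and miR-33b* at least 1.27-fold. These bounds hold for the main scaling alone. Scaling to the spike-ins moved the median Twist1 difference by 0.442 (log2), so the smaller bounds on lower miRNAs may not hold there. The split of 8 higher and 1 lower miRNAs became 12 and 0 when the arrays were scaled to the spike-ins, and 11 and 0 without scaling. With normexp background correction (offset 50) it became 1 and 0, miR-762 being the miRNA left, at 1.03 (log2).

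The second comparison asked the same of Bmi1. let-7i was 2.13-fold higher (log2 difference 1.09, SE 0.04), miR-762 was 7.72-fold higher (log2 2.95, SE 0.05) and miR-1915 was 5.51-fold higher (log2 2.46, SE 0.04). Under normexp correction the log2 differences of miR-762 and miR-1915 were 1.38 and 1.26. Of 194 miRNAs above background on both arrays, 9 were at least 2-fold higher and none was at least 2-fold lower. The remaining 6, chosen after their values were seen, were miR-874 (5.01-fold), miR-1181 (2.93-fold), miR-205 (2.92-fold), miR-638 (2.88-fold), miR-1225-5p (2.82-fold) and miR-584 (2.18-fold). With normexp correction their log2 differences were 0.58, 0.36, 0.27, 0.42, 0.41 and 0.18 in the same order. Over 12 other settings the lowest was 1.53 for miR-874 and 0.74 for miR-584, which is under 2-fold, and at least 1.11 for the other 4. miR-584, like the 5 with 1 probe named for Twist1, had 1 of 2 probes above background on both arrays. The median log2 difference was 0.12 (quartiles -0.07 and 0.31), and 83.5% of the miRNAs lay within 0.5 of 0.

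Within the epithelial list, members of the miR-200 family, which repress ZEB1 and ZEB2, parted in the Bmi1 knockdown. miR-141 was 1.75-fold lower than in the control (log2 difference -0.81, SE 0.03), while miR-200b was at 0.52 (SE 0.03), miR-200c at 0.34 (SE 0.04) and miR-200a at 0.04 (SE 0.02). miR-141 was below 0 and miR-200b above 0 under every setting tried, whereas miR-200c and miR-200a changed sign with the scaling. The median of the 6 measured members was 0.25 (90.5th percentile), which also changed sign with the scaling. Relative to the median of all miRNAs it lay at 0.02 to 0.15 over 10 other settings. The miR-29 median was 0.42 (99.5th percentile), from miR-29a at 0.60 (SE 0.02) and miR-29c at 0.42 (SE 0.02), with miR-29b at -0.18 (SE 0.02). The miR-15/16 median was 0.40 (98.8th percentile), with 4 of 5 measured members higher, among them miR-15b at 0.54 (SE 0.02), and with miR-15a at -0.25 (SE 0.02), while miR-16 at 0.24 (SE 0.02) changed sign with the scaling. Over 10 other settings these 2 list medians exceeded that of all miRNAs by 0.23 to 0.44 and by 0.16 to 0.28. miR-210 was at -0.42 (SE 0.03).

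For the other lists the medians were 0.11 for let-7, 0.07 for the miR-17 to miR-92a list, 0.11 for miR-23/27/24, 0.06 for miR-30, 0.01 for the miR-183 cluster, 0.18 for miRNAs tied to epithelial-mesenchymal transition and 0.24 for miRNAs reported to target Bmi1. None lay outside the central 95% of its random lists, and each of the 7 changed sign under at least 1 other setting. miR-221 was at 0.40 (SE 0.02) and miR-222 at 0.10 (SE 0.04), the latter changing sign with the scaling. 4 miRNAs were above background in the Bmi1 knockdown alone and 25 in the control alone. The lowest normalised probe intensity above background was higher on the Bmi1 array (0.037) than on the control (0.025) or Twist1 array (0.027), and 17 of the 25 had a bound below 1 and 9 were no dimmer on the Bmi1 array, so this count does not show lower levels. miR-150* was at least 5.33-fold higher, miR-939 at least 1.88-fold and miR-532-3p at least 1.81-fold, and miR-301b was at least 1.47-fold lower, miR-130a at least 1.43-fold and miR-34a at least 1.37-fold. Scaling to the 75th percentile of all human probes gave 7 higher and 5 lower miRNAs in place of 9 and 0, and normexp background correction gave 3 and 0. That percentile falls among probes not well above background, since 370 of 2446 human probes were above it on the Bmi1 array.

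**Figure D2:**
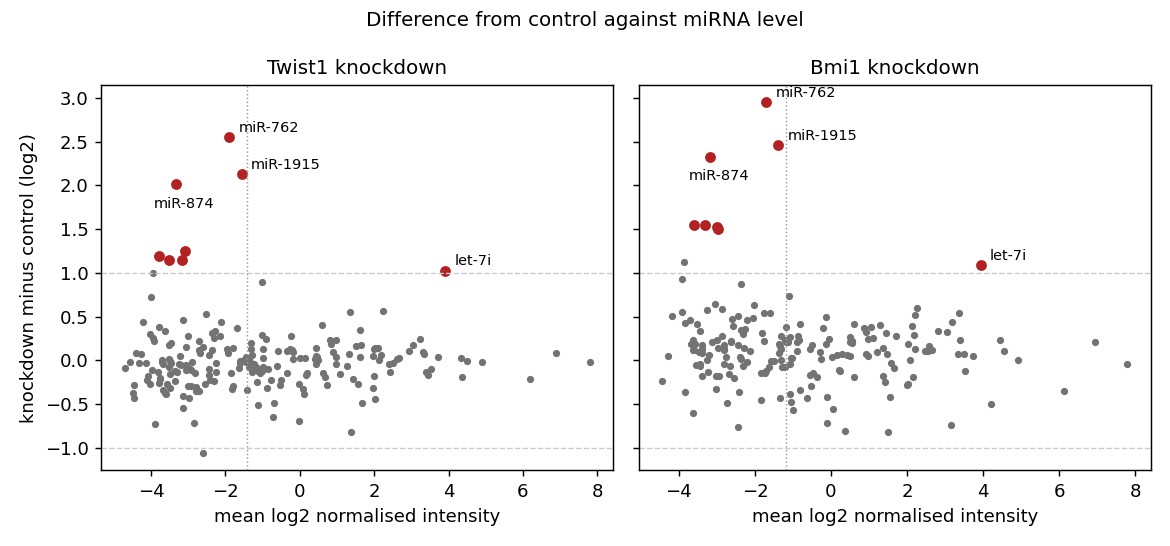
Log2 difference from the control (y axis) against mean log2 normalised intensity (x axis) for each miRNA above background on both arrays, 211 for the Twist1 knockdown and 194 for the Bmi1 knockdown. Red points are the 8 miRNAs at least 2-fold higher in both, dashed lines mark 2-fold and the dotted line the median level. let-7i is the one red point to the right of the median level.

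The direct comparison of the 2 knockdowns does not use the control array. No miRNA of 198 above background on both differed by 2-fold in either direction, and 1 was at least 1.5-fold higher and 1 at least 1.5-fold lower in the Bmi1 knockdown. They were miR-200b* (log2 difference 0.64, SE 0.20) and miR-141 (-0.62, SE 0.03), both keeping their sign under every setting tried and chosen after their values were seen. let-7i differed by 0.07 (SE 0.05), with a sign that depended on the scaling. The median over all miRNAs was 0.17, and 96.5% lay within 0.5 of 0. Of the lists, the cluster from miR-17 to miR-92a and its paralogs lay lowest, with a median of -0.00 for 11 members at the 1.2nd percentile of random lists, whose median was 0.13. The sign of that median depended on how probes were combined. 22 miRNAs were above background in the Twist1 knockdown alone and none in the Bmi1 knockdown alone, but with the higher limit of the Bmi1 array 19 of the 22 had a bound below 1 and 9 were no dimmer there. The largest bounds were for miR-301b (at least 1.22-fold lower in the Bmi1 knockdown), miR-634 (at least 1.04-fold) and miR-215, which was at the limit.

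The 2 knockdowns were compared for how far they share their differences from the control. Of 194 miRNAs, 73.2% differed from the control in the same direction, against 63.5% for simulated unchanged arrays. Both shares belong to the main setting alone. A scaling that moves all differences of a comparison would change the observed share, and the simulated differences were centred at 0. All 8 miRNAs at least 2-fold higher in the Twist1 knockdown were also at least 2-fold higher in the Bmi1 knockdown, where independent lists would share 0.371. Across 194 miRNAs, which are not independent replicates, the log2 differences had a Pearson r of 0.906 and a Spearman rho of 0.779, and r was 0.771 over the 186 miRNAs left without the shared 8. Both comparisons use the same control array, which alone gives a positive correlation. Simulated unchanged arrays with spot noise gave r of 0.464 and a covariance of 0.0016, against an observed covariance of 0.191. Splitting the control spots into 2 sets left r at 0.891, the covariance at 0.189 and the shared miRNAs at 8. Neither calculation covers variation between cultures or between arrays, so part of the excess may come from the shared control. All arrays were on 1 slide, with the control in row 2 and both knockdowns in row 1, so row and control cannot be told apart. With normexp correction 1 miRNA, miR-762, was at least 2-fold higher in both. When dim miRNAs were left out it was another one, let-7i.

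**Figure D3:**
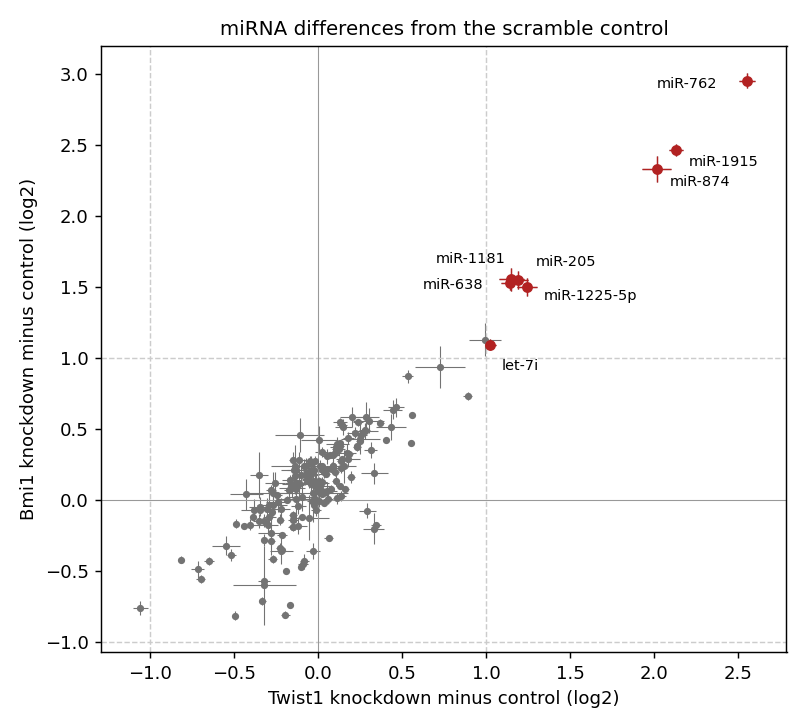
Log2 difference from the control in the Bmi1 knockdown (y axis) against that in the Twist1 knockdown (x axis) for 194 miRNAs, with technical SE bars and dashed lines at 2-fold. The 8 labelled red points are at least 2-fold higher in both, from let-7i at 1.03 and 1.09 to miR-762 at 2.55 and 2.95.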

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

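The values in this part were picked out by fixed rules, and none of the differences was tested. Blank corner spots, which carry no miRNA probe and enter no comparison, gave a total intensity of 32.62 on the Bmi1 array. On the control and Twist1 arrays they were not detected, and their total was at the floor value of 0.1, so no ratio can be taken. Of the 26 such spots, 7 were over 10 intensity units on the Bmi1 array, 2 on the Twist1 array and 0 on the control array, and their medians were -1.81, 0.47 and 0.68.

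Of 51 miRNAs named by the fixed rule and measured on all arrays, 5 lay on opposite sides of the control in the Twist1 and Bmi1 knockdowns, each by more than 2 technical SE. Of all 194 measured miRNAs, 15 did. With 1 array per group this was not tested. miR-29b, of the miR-29 family, was at 0.35 in the Twist1 knockdown and -0.18 in the Bmi1 knockdown, a Bmi1 minus Twist1 difference of -0.524. It was the one of the 5 whose 2 signs held under every setting tried. miR-30e* differed by 0.429 between the knockdowns, miR-30c by 0.258, miR-222 by 0.219 and miR-24 by 0.205, all lower than the control in the Twist1 knockdown and higher in the Bmi1 knockdown. The signs of these 4 depended on the scaling.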

How the results depend on the processing

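The alternatives were fixed before the data were examined, except 4 chosen after seeing them: let-7i relative to the other let-7 members, the correlation without the shared miRNAs, the split of the control spots and exact list names. Where no cause is named, the cause was not tested. The number of miRNAs at least 2-fold higher than control (8 for Twist1, 9 for Bmi1) became 1 and 3 with normexp, and 1 and 1 when miRNAs below the median level were left out, a filter that keeps 106 and 97 miRNAs. Bmi1 had 16 with no filter and 15 at 1.5-fold. The number at least 2-fold lower (1 and 0) became 0 for Twist1 with normexp, spike-in scaling, no scaling and the level filter, 2 with no filter and 6 at 1.5-fold. For Bmi1 it became 5 with the 75th percentile of all human probes, 1 with the software's detection call, 2 with no filter and 6 at 1.5-fold. Between the knockdowns, 0 higher and 0 lower became 1 higher with gene-level totals, the series table, no filter and 1.5-fold, and 1 lower with the detection call and 1.5-fold.

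let-7i was higher than control under each of these settings, but not always by 2-fold (1 on the log2 scale). In the Twist1 knockdown it was 0.99 with normexp, 0.96 with all human probes, 0.82 with quantile normalization, 1.47 with spike-ins, 1.34 unscaled, 0.97 with the brightest probe, gene-level totals or the series table, and 1.08 relative to the other members. In the Bmi1 knockdown it was 1.03 with normexp, 0.70 with all human probes, 0.98 with median scaling, 0.99 with quantile normalization, 1.15 with spike-ins, 1.14 with outlier spots kept and 1.03 relative to the other members. The correlation of the knockdowns (0.906) became 0.776 with normexp, 0.778 with the level filter and 0.771 without the shared miRNAs. The shared miRNAs (8) became 1 with normexp (miR-762) and 1 with the level filter (let-7i).

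Some settings moved the median of all miRNAs by over 0.1. For Twist1 the shifts were 0.442 (spike-ins), 0.314 (no scaling), 0.141 (no filter) and -0.152 (normexp). For Bmi1 they were 0.478 (no filter), -0.390 (all human probes), -0.109 (median) and -0.138 (quantile). Between the knockdowns the shifts were 0.311 (no filter), -0.328 (all human probes), -0.114 (median), -0.130 (quantile), -0.381 (spike-ins) and -0.348 (no scaling). The no-filter setting covers all 887 miRNAs, with low values set to a floor. The lowest level above background was 0.025 on the control array, 0.027 on the Twist1 array and 0.037 on the Bmi1 array. The no-filter shifts thus need not reflect measured differences. The median of the miR-17 to miR-92a list between the knockdowns (-0.00) was reversed with log2 probe means (0.012), the brightest probe (0.0023), gene-level totals (0.056) and the series table (0.056). Relative to the median of all miRNAs it lay between -0.261 and -0.118 over 10 settings.

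With exact names, the list of other small RNA sequences had a Bmi1 median of -0.351 over 9 members (0.010th percentile), against -0.01 over 11 (7.58th). The remaining values are each 1 list median, or the difference of miR-762 or miR-1915, in 1 comparison under 1 other setting. Of these, 81 values of list medians and 30 of the single miRNAs moved by more than the SD of the members or the technical SE. 298 and 22 values did not. Signal over background limits what can be said of the dim miRNAs. No paired analysis was possible because each group has 1 array.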

Other observations

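The tests of explanations in this part were chosen after the results were seen, and the percentiles of the fixed lists before the data were examined. Sequences listed as miRNAs but derived from other small RNAs were among the brightest features. miR-1274a, from a lysine tRNA, had a log2 difference from control of -0.49 (SE 0.02) in the Twist1 knockdown and -0.82 (SE 0.03) in the Bmi1 knockdown, below 0 under every setting tried. miR-1246 was at -0.81 (SE 0.02) and -0.42 (SE 0.03), also below 0 throughout, and was chosen after its values were seen. miR-720 was at -0.22 (SE 0.02) and -0.35 (SE 0.03), and miR-1274b at -0.19 (SE 0.02) and -0.50 (SE 0.01), both changing sign for Twist1 under another scaling. miR-1974 was at 0.08 (SE 0.01) and 0.21 (SE 0.03), the latter changing sign with the scaling. The place of the whole list depends on 2 suffixed names, miR-1974 and miR-1977, which were matched only after the list's values had been seen. With them the Bmi1 median was -0.01 over 11 members, at the 7.58th percentile of random lists, and without them -0.35 over 9 members, at the 0.010th. The medians with and without them were, for Twist1, -0.01 (38.0th percentile) and -0.08 (8.06th), and between the knockdowns 0.04 (5.91st) and -0.01 (3.04th). The list is therefore not reported as standing apart. The star strands, the usually less abundant arm of a hairpin, had medians of -0.10 over 33 members in the Twist1 knockdown (3.99th percentile) and 0.11 over 28 in the Bmi1 knockdown (7.09th), with signs that depended on the scaling. Over all lists, 38 medians were placed among random lists, of which 4 lay above and 1 below the central 95%.

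let-7i was higher than control in both knockdowns. A scaling factor common to an array is argued against, since it cannot part let-7i from the other 8 members. let-7i exceeded their median by 1.08 in the Twist1 knockdown and 1.03 in the Bmi1 knockdown. With quantile normalization, the one scaling of 6 that is not such a factor, the excess was at least 0.875. Cross-hybridisation with another member and a few deviant spots are argued against too: under the main scaling no other member was above 0.136 in either comparison, and 0 knockdown spots lay below the highest control spot of the same probe. A difference of single cultures or arrays stays open with 1 array per group, and cannot be told apart from an effect of either knockdown. An effect of the knockdowns on let-7i is thus a hypothesis these data cannot settle.

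7 other miRNAs, led by miR-762 and miR-1915, were at least 2-fold higher in both knockdowns. A uniform background offset between arrays is argued against: with each array's negative control mean (0.101, 0.885 and 1.34 intensity units) taken off every probe, the lowest of their log2 differences was 1.11. This does not cover a local offset, which was not tested. Single blank corner spots reached 30.94 on the Twist1 array and 78.89 on the Bmi1 array, against 3.79 on the control array. Of 26 such spots, 2, 7 and 0 were over 10 units. The smallest gains of the 7 miRNAs ran from 28.3 to 230.7 units. An effect shared by dim miRNAs in general is argued against, since level-matched random lists without the 7 had medians of -0.051 and 0.125 (upper limits 0.196 and 0.413). The 7 had medians of 1.25 and 1.55, but they were chosen as high in these data. The contrast between them and the lists was thus fixed by the choice and is no further evidence. An effect on some dim miRNAs alone stays open, since 0 of the 7 had a mean level at or above the median. Normexp correction, with medians of 0.15 and 0.42, does not decide this, as its offset of 50 shrinks the differences of miRNAs with control intensities of 15.4 to 52.7 whatever their cause. GC-rich sequence stays open. Outside the 7, 9 miRNAs taken to be GC-rich from memory, without sequences, had a median of -0.257 in the Twist1 knockdown (1.32nd percentile of level-matched lists, 4 of 9 higher). In the Bmi1 knockdown it was 0.118 (26.3rd, 6 of 9 higher), and single members reached 0.534 and 0.869. The 9 were chosen after values were seen and without the raised miRNAs, so these medians cannot decide for or against it. A low reading on the control array, alone in its row of the slide, stays open too. Between the knockdowns the 7 differed by a median of 0.357, against 0.199 for random lists (99.9th percentile, upper limit 0.299), an excess that is small beside 1.25 and 1.55. Before scaling they differed by 0.009 (-0.098 to 0.054), against -0.189 for 191 other miRNAs. The 7 thus had nearly the same unscaled intensity on both arrays of row 1. The excess over other miRNAs therefore does not decide about a low control reading. How large a value would argue against this was set after the value was seen. A low control reading cannot be told apart from an effect common to both knockdowns, which was not tested.

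miRNAs from neighbouring genes had similar differences from control on average. Over 41 pairs of hairpin genes within 10 kb of each other, the mean absolute difference between neighbours was 0.150 in the Twist1 knockdown, against 0.398 for random placements, and over 37 pairs 0.218 in the Bmi1 knockdown, against 0.428. Of 10000 placements within 3 bins of level, 0 and 9 were as low, placing the observed values at most at the 0.09th percentile. Shared transcription of neighbouring genes is a hypothesis for this, and cross-hybridisation between related sequences stays open. Pairs of unrelated neighbours (18 and 15) also lay low, at most at the 0.41st percentile. Pairs that share a gene are not independent. Not every pair was alike: the neighbours miR-141 and miR-200c were at -0.81 and 0.34 in the Bmi1 knockdown. No pair holds a miRNA at least 2-fold higher in both knockdowns, but these miRNAs are among those placed at random. Random placements thus include large differences that the pairs cannot. The percentiles therefore overstate how alike neighbours were, and they cannot decide between the 2 explanations.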
